A study of Caenorhabditis elegans with 2 samples.

How the data were processed

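ChIP-seq peaks were analysed from whole L1 larvae of strain OP106, in 2 biological replicates of 1 group, with eGFP-tagged MDL-1 as the protein precipitated, per the labels. Library fragments were selected between 150 and 350 bp, per the labels. Extraction details, the aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Per the deposited file inventories, the authors aligned reads to ce10 and ce11 and called relaxed peaks separately in each replicate and on the pooled replicates. From these they made an optimal IDR-thresholded list for each build. The inventories name a control for the pooled list in ce11 and for the replicate lists in ce10, and no control file for the replicate lists in ce11. Alignments, coverage tracks and the control were not used here.

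Each deposited list gives a position, a score, a q-value column and a summit per peak. The score is the authors' caller's own value for the peak, and its scale is not given in the sources used here. The deposited q-value column is on the −log10 scale by its format. It saturates at 3.88 in the IDR list, where 3801 peaks share that value, so it was used for no ranking. Scores were used to rank and filter peaks within a list. Because the scores of different lists share no stated scale, no mean and SD is given. Ranks in both replicates are given for the highest peaks, for some network genes and for other list members below the highest 3870 in a replicate, and other list members are given by pooled score only. The IDR list in ce11 was exactly the 3870 highest-scoring peaks of the pooled list, and that in ce10 the 4008 highest. Relaxed lists end at 30000 peaks, so a peak missing from one is only below its end. Peak widths came mostly from 1 value per list (310 bp in the pooled list, 320 bp in replicate 1, 296 bp in replicate 2), so summits and not intervals were compared. Depth is unknown, since the lists carry no read counts, and it is not known which replicate was deeper.

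Coordinates are those of ce11, 1-based. The reference was WBcel235 with Ensembl release 115 annotation, which is the sequence of ce11: the 6 nuclear chromosomes have the same names, and no peak ends beyond the length of its chromosome. The ce10 lists were used only for alternatives that need no annotation. A promoter window ran from 1000 bp upstream to 200 bp downstream of the 5' end of each of 19973 protein-coding genes. A summit outside these windows was called coding, untranslated, intronic or intergenic, in this order. Gene lists (33) were fixed before the data were examined, by name or name pattern. The chemoreceptor pattern also took in 9 genes with other functions, such as serpins, none of which had a promoter peak.

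The promoter share, tRNA and microRNA counts and the shared top peaks were tested by 1000 random placements of summits within their own chromosome. The X ratio was tested by 100000 placements in proportion to protein-coding promoters. All permutation tests were two-sided, with 2 times the smaller tail as p. Gene lists and motifs were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 33 lists or the 26 hexamers, at 0.05. Motifs were searched within 50 bp of the summit, against the same windows moved by 500 bp to either side. Intervals for shares are exact Clopper-Pearson 95% intervals and cover counting error only, since reads copied by PCR are not independent molecules. Peaks and genes are not replicates, so these tests describe these lists and do not measure the spread between animals. With 2 replicates no test of outliers was possible.

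Genes named in the text followed a rule fixed before the data were examined: the 25 protein-coding genes with the highest-scoring promoter peak that both replicates also had within 100 bp, each peak given to the nearest 5' end; all 6 members of the MAD, MAX and Mondo network; up to 4 members of every other list; and up to 4 tRNA and 4 microRNA genes. Of the list members that the rule picks, 1 is not reported here. The highest peaks outside promoters, further peaks of network genes and the genes around mdl-1 were chosen after their values were seen. Alternatives covered stricter and looser peak sets, each replicate alone, other windows and distances, other backgrounds and the ce10 lists.

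The tests were checked on simulated data on the real annotation. In 50 sets of randomly drawn genes, 1 of 50 had any list called. With 3 lists given peaks at raised rates in each of 50 sets of 19973 genes, all 150 planted lists were called, beside 5 calls of other lists. Both checks drew genes without regard to upstream length or to peaks shared by neighbours. They therefore cannot show how often lists are called wrongly where genes share peaks. Of 50 random peak sets, placed uniformly as in the test itself, 3 had a promoter permutation p under 0.05. With 10% of 3870 random peaks moved to a CACGTG site, the excess over the flanks came to 9.67%. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.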

Results

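Binding of MDL-1 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in L1 larvae, the first larval stage of the nematode Caenorhabditis elegans. MDL-1 is the worm's MAD-like basic helix-loop-helix leucine zipper protein, which binds the E-box CACGTG as a dimer with MXL-1. The strain, OP106, carries an integrated transgene (wgIs106) for mdl-1 fused to eGFP, and whole animals of both sexes were used. The series holds 1 group of 2 biological replicates, so replicate 1 against replicate 2 is the only comparison between samples. The other comparisons set the peaks against the genome: where they lie, which genes they lie beside and which DNA sequence they hold. The files give no read totals, so sequencing depth was unknown. The authors' optimal list after irreproducible discovery rate (IDR) filtering held 3870 peaks in the ce11 build. Their pooled scores ran from 32.7 to 679.7, with a median of 58.8. The relaxed lists of replicate 1, of replicate 2 and of the pooled replicates each held exactly 30000 peaks.

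The 3 peaks of highest score lay outside protein-coding promoter windows. The highest, with a pooled score of 679.7, had its summit at chromosome IV, position 11956501, in intergenic sequence 3252 bp downstream of the nearest 5' end, that of the glutamate dehydrogenase gene gdh-1, and beyond the end of that gene. It held CACGTG, and an annotated non-coding RNA, ZK829.13, lay within 200 bp. The next lay at chromosome III, position 3801518, 1051 bp upstream of mtm-3, with a score of 633 and no CACGTG. The third lay in an intron of Y43F8B.2 at chromosome V, position 19529400, with a score of 629 and a CACGTG. These peaks ranked 3, 6 and 4 in replicate 1 and 2, 3 and 4 in replicate 2. Introns of nhr-19, a nuclear hormone receptor gene, and of the autophagy gene epg-9 held the peaks ranked 8 and 10, with scores of 607 and 502.

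Among peaks in promoter windows, the highest stood at ipla-6 (WBGene00022233), a gene for a phospholipase of the calcium-independent family. Its peak spanned positions 6336683 to 6337072 of chromosome IV in ce11, with the summit 786 bp upstream of the gene's 5' end and a CACGTG within 50 bp. The pooled score was 626, and the peak ranked 11 in replicate 1 and 1 in replicate 2. The peak of tasp-1 (WBGene00010480), at 10759116 to 10759449 of chromosome III, had its summit 22 bp upstream of the 5' end, a score of 623 and no CACGTG. It ranked 2 in replicate 1 and 10 in replicate 2. C36E6.2 (WBGene00016490), on chromosome X, had a peak at 17451465 to 17451717 with a CACGTG and a score of 514. Its ranks were 14 and 6. The fourth, at iff-2 (WBGene00002065), which encodes the translation factor eIF5A, lay at 8561317 to 8561553 of chromosome II with a score of 498, no CACGTG and ranks of 17 and 9.

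The 25 genes of highest peak score included members of the fixed lists and others, described here by what is known of each gene and not tested as groups. Of the translation lists, they held iff-2, the ribosomal protein genes rpl-15, rpl-3 and rps-1, with scores of 463, 373 and 330.3, and the elongation factor gene eef-1A.2, with 327. Also among them were ztf-7 (492), puf-9, a Pumilio RNA-binding protein gene (462), the histone acetyltransferase gene cbp-1 (354), the helix-loop-helix gene hlh-11 (347) and the zinc finger gene zfp-3 (329). The enzyme genes ipla-6, the alcohol dehydrogenase gene adh-1 (423), the acyl-CoA synthetase gene acs-2 (369) and the tyrosine aminotransferase gene tatn-1 (362) were further members. The stress and immunity kinase-like gene nipi-3 had a score of 355 and the protein-unfolding ATPase gene cdc-48.1 had 333. The others were tasp-1, C36E6.2, K02A6.3, tag-340, F56C9.10, epn-1, R107.5, mans-3 and ska-3, and the ska-3 peak also lay in the promoter window of the ribosomal protein gene rps-12. Scores of the 25 peaks ran from 327 to 626. All 25 ranked 66 or better in replicate 1 and 98 or better in replicate 2, and 9 of the 25 genes were on chromosome X. CACGTG lay within 50 bp of the summit in 6 of them, at ipla-6, C36E6.2, adh-1, F56C9.10, tatn-1 and R107.5.

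The members of the MAD, MAX and Mondo network, to which MDL-1 belongs, had an IDR summit in the promoter window at 2 of 6 genes, against 12.8% of other protein-coding genes (odds ratio 3.40, Fisher's exact test, adjusted p = 0.249), which did not pass the test. The partner gene mxl-1, mxl-2 and mdl-1 itself had none in the promoter window or the gene body. The gene mxl-3 (chromosome X, 13349639 to 13350804) had 2 promoter peaks with scores of 54.3 and 53.0, the first holding CACGTG. They ranked 2381 and 1495 in replicate 1, and 1563 and 4798 in replicate 2. The Mondo-like gene mml-1 (chromosome III, 7370130 to 7374731) had 2, with scores of 49.4 and 40.8, the second holding CACGTG. These ranked 1754 and 2296 in replicate 1, and 4771 and 5004 in replicate 2, below the highest 3870 there. The TFEB-like gene hlh-30 (chromosome IV, 4014793 to 4034951) had none in its promoter window but 7 in its introns, 3 of which ranked below the highest 3870 in replicate 2. The strongest of these, at position 4024335, scored 183 and ranked 237 in replicate 2. With the 7740 highest pooled peaks or with replicate 1 alone, the network list passed the test.

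Of the lists for protein synthesis, all but the aminoacyl-tRNA synthetases had promoter peaks more often than other genes. Of 81 cytosolic ribosomal protein genes, 69 had an IDR summit in the promoter window (85.2%, exact 95% interval 75.6 to 92.1%; odds ratio 40.2, Fisher's exact test, adjusted p = 2.9e-48). With each peak given to the nearest 5' end only, the odds ratio was 9.69 (exact adjusted p = 1.5e-19). The highest scores were those of rpl-15, rpl-3, rps-12 and rps-1. Translation initiation and elongation factors had peaks at 20 of 38 genes (52.6%, exact adjusted p = 2.9e-08), led by iff-2, eef-1A.2, eef-1A.1 and eef-1G, with scores of 498, 327, 241 and 179.6. Nucleolar and rRNA processing genes had peaks at 10 of 24 (41.7%, exact adjusted p = 0.00106), led by the fibrillarin gene fib-1 with a score of 106, then nol-56, nol-10 and pro-1. Mitochondrial ribosomal protein genes had peaks at 21 of 70 (30%, exact adjusted p = 0.000563), led by mrps-7 with 178, mrpl-49, mrpl-28 and mrpl-23, a call that was lost among the 1935 highest IDR peaks. Aminoacyl-tRNA synthetase genes, at 8 of 31, did not pass the test (exact adjusted p = 0.0953), and their highest scores were those of ears-2, hars-1, aars-1 and fars-1, from 74.5 down to 52.6.

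Oxidative phosphorylation, chaperone, proteasome, autophagy and vacuolar ATPase genes had promoter peaks more often than other genes, while lysosomal, glycolysis and fatty acid genes did not pass the test. Oxidative phosphorylation genes had promoter peaks at 20 of 38 (exact adjusted p = 2.9e-08), led by cox-5A, sdha-1, cox-5B and atp-1, with scores of 215, 194, 160.2 and 152. Chaperone and heat shock genes had peaks at 26 of 59 (44.1%, odds ratio 5.40, or 2.63 with nearest 5' ends only, exact adjusted p = 2.9e-08 and 0.0157), led by hsp-3, the endoplasmic reticulum BiP homologue, with a score of 282, then cct-1, dnj-13 and hsp-60. Proteasome genes had peaks at 16 of 33 (48.5%, exact adjusted p = 2.8e-06), led by rpn-3 with 125, rpt-2, pbs-1 and rpn-9. Autophagy genes had peaks at 14 of 31 (45.2%, exact adjusted p = 3.6e-05), with scores of 278 at lgg-2, 277 at atg-9, 274 at lgg-1 and 274 at epg-7. Peaks at atg-9 and epg-7 held CACGTG. Genes of the vacuolar ATPase had peaks at 7 of 20 (exact adjusted p = 0.0210), led by vha-12, vha-8, vha-1 and vha-15, but this call was lost with random lists matched on upstream length (permutation adjusted p = 0.0817) and among genes with a letters-number symbol. Lysosomal genes (5 of 40), glycolysis genes (4 of 19) and fatty acid genes (7 of 54) did not pass, with adjusted p of 1, 0.404 and 1 by Fisher's exact test. Single peaks there were still high, as at acs-2 (369), acdh-9 (152), the hexokinase gene hxk-3 (181) and cpr-9 (101).

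Cell cycle and muscle genes also carried peaks more often than other genes. Of 34 cell cycle and DNA replication genes, 14 had one (41.2%, exact adjusted p = 0.000116), led by the F-box gene lin-23 with a score of 244, cdc-6 with 103, the E2F-like gene efl-1 with 99.5 and wee-1.3 with 97.3. Of 28 body wall muscle genes, 11 had one (39.3%, exact adjusted p = 0.00106). The muscle peaks were lower, with scores of 74.3 at act-2, 59.7 at tnt-2, 59.1 at unc-112 and 46.4 at the myosin gene unc-54, and the muscle call was lost among the 1935 highest IDR peaks. The unc-54 peak had no relaxed summit in replicate 2.

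Several large gene families had few promoter peaks. Seven-transmembrane chemoreceptor genes had them at 15 of 1365 (1.1%, exact adjusted p = 1.7e-60), among them srh-17, srh-2 and srh-16 with scores of 131 down to 95.5. F-box genes had them at 11 of 322 (3.42%, exact adjusted p = 3.6e-08), led by fbxb-58 and fbxb-85, with 134 and 125. C-type lectin genes had them at 6 of 240 (2.5%, exact adjusted p = 1.3e-07), led by clec-140 with 102. Cuticle collagen genes had them at 10 of 170 (5.88%, exact adjusted p = 0.0124), led by col-38 with 121. Neuropeptide genes had them at 5 of 102 (exact adjusted p = 0.0236), led by nlp-34 and nlp-31, which share a peak of score 52.1. The neuropeptide call was lost with random lists matched on upstream length (permutation adjusted p = 0.140) and when each peak was given to the nearest 5' end only.

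The remaining lists did not pass the test at 0.05, though several passed under another setting. With the 7740 highest pooled peaks these were synthetases, histones, insulin-like peptides, heterochronic genes and nuclear receptors, of which the last 2 also passed with replicate 1 alone. With a window of 2000 bp upstream they were synthetases, insulin-like peptides, homeobox, glycolysis and insulin and TOR genes. Histones passed as lower with random lists matched on upstream length (7 genes against 15.5, permutation adjusted p = 0.0220), nuclear receptors with nearest 5' ends only, insulin-like peptides and homeobox genes among genes with a letters-number symbol, and heterochronic and insulin and TOR genes with every transcript 5' end. Germline markers had peaks at 0 of 22 genes (exact adjusted p = 0.161, exact upper limit 15.4%), insulin-like peptides at 1 of 39 (ins-39, exact adjusted p = 0.0953) and ceh homeobox genes at 3 of 63 (ceh-38, ceh-39 and ceh-20, exact adjusted p = 0.0953). Heterochronic timing genes had them at 4 of 12 (exact adjusted p = 0.0953), namely lin-66, lin-14, lin-28 and lin-46. Nuclear hormone receptor genes had them at 43 of 269 (exact adjusted p = 0.178), led by nhr-32, nhr-49, nhr-35 and nhr-1 with scores of 249.7 down to 159. Regulators of insulin signalling, TOR and lifespan had them at 4 of 20 (akt-2, daf-16, daf-15 and smk-1, exact adjusted p = 0.413). Histone genes had them at 7 of 72 (his-37, his-67, his-68 and his-72 the highest, exact adjusted p = 0.727) and bHLH genes at 2 of 32 (hlh-11 and mxl-3, exact adjusted p = 0.538). Tissue markers of the intestine (1 of 18, act-5), pharynx (1 of 16, tbx-2), hypodermis (2 of 23, nhr-25 and dlg-1) and neurons (4 of 38, snb-1, ric-19, egl-3 and unc-33) had adjusted p from 0.819 to 0.864 by Fisher's exact test. Of the list members named, hars-1, daf-15, smk-1, tbx-2, dlg-1, unc-33 and lin-46 ranked below the highest 3870 in replicate 2, at 9261, 6260, 3898, 7746, 13721, 10167 and 9873, and at 878, 1401, 3746, 3129, 2560, 3418 and 2091 in replicate 1. Of 33 lists, 16 passed. Neighbouring genes can share a promoter peak, so genes are not independent and these p-values are too small to that extent.

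**Figure D1:**
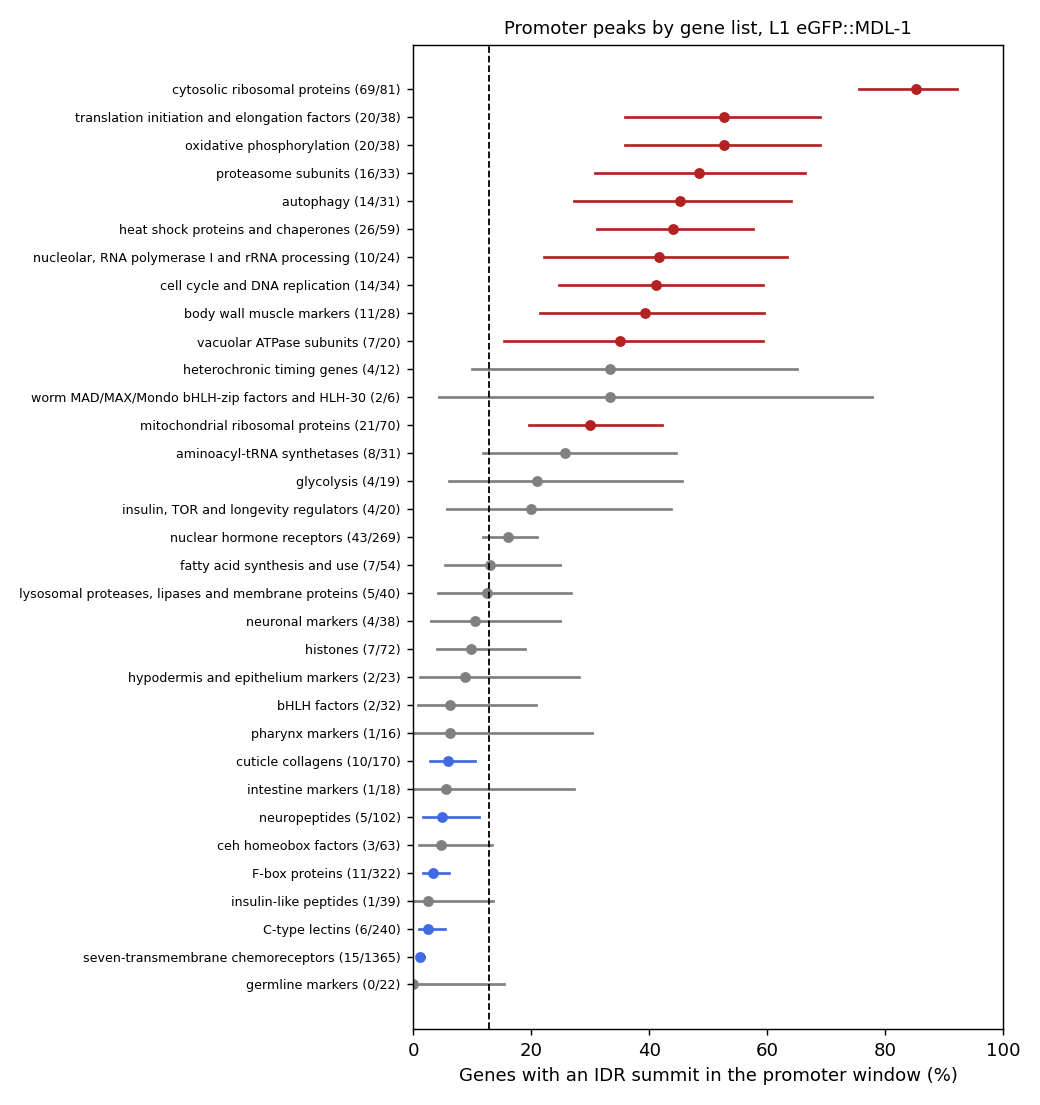
Share of genes with an IDR summit from 1000 bp upstream to 200 bp downstream of the 5' end, in percent, for each of 33 gene lists, with exact 95% intervals for counting error; red lists were higher and blue lists lower than other genes at an adjusted p under 0.05, grey lists did not pass, and the dashed line is the share among all 19973 protein-coding genes. Ribosomal protein genes stand at 85.2% and chemoreceptor genes at 1.1%, against 12.8% of all genes.

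Just over 50% of the peaks stood at promoters. Of the 3870 IDR summits, 51.2% lay in a protein-coding promoter window, against 21% for summits placed at random on the same chromosome (random range 19.8 to 22.4% in 95% of placements; permutation p = 0.002, the smallest that 1000 placements can give). These summits lay a median of 196 bp from the nearest 5' end, and 2560 of 19973 protein-coding genes (12.8%) had at least 1. Coding exons outside promoter windows held 0.982% of summits against 20% at random, introns 21.4% against 30.8%, and untranslated regions 1.63% against 3.09% (permutation p = 0.002 each, adjusted p = 0.0025). Intergenic sequence held 24.8% against 25.09%, a difference that did not pass the test (permutation p = 0.655). Random placement ignores which sequence can be mapped.

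CACGTG was found near 13.2% of IDR summits, against 1.94% of windows moved by 500 bp. That was 509 of 3870 peaks (exact 95% interval 12.1 to 14.3%) and 150 of 7740 flanking windows, an odds ratio of 7.66 (Fisher's exact test, p = 2.1e-125, adjusted p = 5.4e-124 over 26 hexamers). This was the highest odds ratio of the 26 palindromic hexamers compared. CAGCTG, the E-box of other helix-loop-helix proteins, stood at 3.70% against 2.26% (odds ratio 1.66, exact adjusted p = 4.2e-05). CATATG and CAATTG did not pass the test against the flanks, at 1.83% against 1.85% and 4.19% against 4.21% (exact adjusted p = 1 and 0.999). The next highest after CACGTG were ACGCGT, with an odds ratio of 4.49, and TGCGCA, with 4.21. In the highest quartile of pooled score, 20.9% of peaks held CACGTG, then 13.2%, 9.31% and 9.20% in the lower quartiles. Top and bottom quartile differed with an odds ratio of 2.60 (Fisher's exact test, p = 6.0e-13). The hexamer was less common at promoter peaks (10.2%) than at intronic (17.3%) and intergenic peaks (15.1%).

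**Figure D2:**
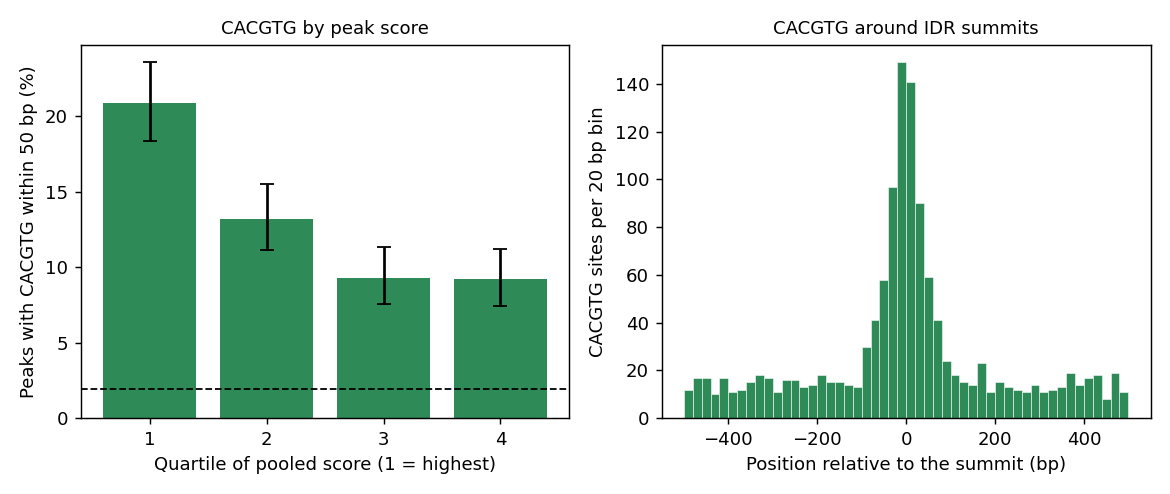
Left, percent of IDR peaks with CACGTG within 50 bp of the summit in each quartile of pooled score (1 is the highest), with exact 95% intervals for counting error and the flanking level of 1.94% as a dashed line; right, number of CACGTG sites in bins of 20 bp by position relative to the summit in bp. The share falls from 20.9% in the highest quartile to 9.20% in the lowest, and the sites gather at the summit, with 149 and 141 in the 2 central bins.

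Chromosome X carried more peaks per Mb than the autosomes together. It held 853 IDR peaks, or 48.1 per Mb, against 36.5 per Mb on chromosomes I to V, a ratio of 1.32. Placements in proportion to the number of protein-coding promoters gave a ratio of 0.738 on average, between 0.672 and 0.806 in 95% of them (permutation p = 2.0e-05, the smallest that 100000 placements can give). Among the autosomes, density ran from 29.2 per Mb on V to 46.9 on III. Per Mb of whole chromosome, promoter peaks were about as dense on X as on autosomes (20.4 against 19.6). Intergenic peaks stood at 15.6 against 8.26 and intronic peaks at 10.4 against 7.80 on the same scale. X had fewer protein-coding genes per Mb (154 against 209), and the length of intergenic and intronic sequence on it was not taken into account. Of X genes, 13.9% had a promoter peak, against 12.6% of autosomal genes (odds ratio 1.12, Fisher's exact test, p = 0.0691).

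**Figure D3:**
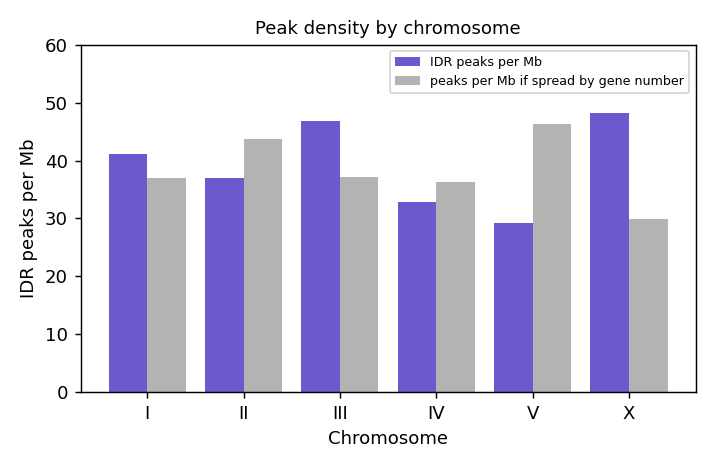
IDR peaks per Mb on each nuclear chromosome (blue bars) beside the density that the same total would give if spread by the number of protein-coding genes (grey bars). Chromosome X stands at 48.1 peaks per Mb and chromosome V at 29.2.

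Genes for small RNAs also had peaks. Of 612 tRNA genes, 225 (36.8%, exact 95% interval 32.9 to 40.7%) had an IDR summit within 200 bp, against 11.9 at random (permutation p = 0.002, the smallest possible). The highest scores were 208 at F29C4.t1 (chromosome IV, 143982 to 144054), 159.6 at C28G1.t1 and 146 at C33G3.t2 (both chromosome X), and 149 at ZK783.t1 (chromosome III). The peaks at F29C4.t1 and ZK783.t1 held CACGTG, and the other 2 did not. Of 261 microRNA genes, 36 (13.8%, exact 95% interval 9.85 to 18.6%) had a summit in the gene or within 1000 bp upstream, against 11.3 at random (permutation p = 0.002). The highest was a peak of score 347 with CACGTG, at position 13145376 of chromosome X, upstream of the clustered genes cel-mir-54, cel-mir-55 and cel-mir-56. The next, with 303 and also with CACGTG, lay at cel-mir-5595 on chromosome II. Among classes looked at after the main results were known, 93 of 346 snoRNA genes had a summit within 200 bp, against 7.24 at random (permutation p = 0.002, adjusted p = 0.00333 over 5 RNA classes), and 15 of 129 snRNA genes, against 2.44 (permutation p = 0.002). Of microRNA genes, 10 had a summit within 200 bp, against 5.23 at random, which did not pass (permutation p = 0.150, adjusted p = 0.187). Of 20 rRNA genes, 0 had one. These placements ignored the gathering of peaks at protein-coding promoters, and genes far from protein-coding 5' ends were examined apart for tRNA genes only. Neighbouring small RNA genes can also share a peak, as cel-mir-54, cel-mir-55 and cel-mir-56 did.

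Replicates shared most of their highest peaks. Of the 3870 highest peaks of replicate 1, 2607 (67.4%, exact 95% interval 65.9 to 68.8%) had a summit within 100 bp of one of the 3870 highest of replicate 2, against 0.798% for random placements (permutation p = 0.002, the smallest possible). Both replicates had a relaxed summit within 100 bp of 3657 IDR peaks (94.5%). Across these peaks, which are not independent replicates, the scores had a Spearman rho of 0.603. The CACGTG share differed between the replicates' lists: 14.3% of the highest 3870 peaks in replicate 1 (exact 95% interval 13.3 to 15.5%) and 10.1% in replicate 2 (9.17 to 11.1%). With 1 group of 2 samples, this difference can be set against no other replicate spread.

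**Figure D4:**
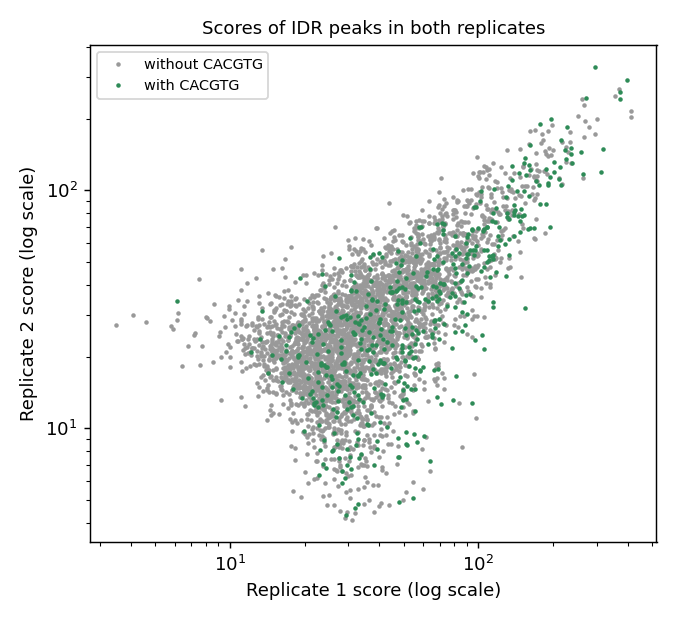
Score of each of 3657 IDR peaks in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), both as the authors' caller gave them, with peaks that hold CACGTG within 50 bp of the summit in green and others in grey. The scores rise together with a Spearman rho of 0.603 across peaks.

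The genomic locus of mdl-1 itself (chromosome X, 6742351 to 6743899) held no relaxed peak. In the 40 kb window centred on the gene, the pooled list had 0 summits, against a median of 12 over 2503 such windows, and 1.72% of windows held as few. Replicate 1 had 3 summits there, the highest with a score of 4.28, and replicate 2 had 0, against medians of 11 and 12. The span without pooled peaks ran from 6702350 to 6764698, which is 62.3 kb, and held acr-2, acr-3, nas-11, smf-2, smf-1, slc-25A10, K11G12.6, R03E9.2, mdl-1 and abts-4.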

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

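With 1 group of 2 samples, no test for an outlying sample was possible, and the patterns weighed here are 3 of the report. The test of extra copies raising reads at mdl-1 was fixed before the data were examined. The test of extra control copies was chosen after the values at mdl-1 were seen. The tests of the tRNA, ribosomal protein and chromosome X patterns were chosen after those patterns were seen, but before the values the tests measure were computed, except that the peaks of rpl-15 and rpl-3 were already known to lack CACGTG. The design names no contrast that would give a biological explanation, so none was tested.

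The strain carries extra copies of mdl-1, which may raise reads over the gene's own region. The test looked for many relaxed peaks there, and the pooled list held 0 in the 40 kb window, below the median of 12. Extra peaks were therefore not seen. A control is named for the pooled list, and it was not examined here and may carry the same copies. The count of peaks thus cannot show whether reads over the gene were raised. A candidate explanation in the other direction is that extra copies in the control lowered the net signal. The span without pooled peaks at mdl-1 is matched or exceeded by 0.100% of 29994 spans. A span picked because it holds a given gene is more often a long one, so this share makes the locus look rarer than it is. In the pooled list and in both replicates, the window held fewer peaks than the median of windows with as many promoters. Of those 244 windows, 1.64% held as few in the pooled list, 2.87% in replicate 1 and 0.410% in replicate 2. The explanation stays open, because it came from these values and longer peak-free spans lie elsewhere, the longest 146 kb on chromosome V.

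Ribosomal protein promoters and tRNA genes carried peaks far more often than chance, a pattern that signal at highly transcribed genes without the factor's own motif could give. CACGTG lay at 5 of 279 such peaks (1.79%) against 10.6% of other promoter peaks, an odds ratio of 0.153 (exact 95% interval 0.0488 to 0.369), which is consistent with that explanation. Most of these peaks were at tRNA genes (3 of 211, odds ratio 0.121, with 2 of the 3 among the 4 tRNA genes of highest score), and ribosomal protein promoters alone gave 2 of 68, an odds ratio of 0.254 with an interval of 0.0300 to 0.969. The octamer AGACGCAG, chosen after the main results were seen, was also less common at these 279 peaks. It lay at 6 of them (2.15%) against 12.8% of other promoter peaks, an odds ratio of 0.149 (exact 95% interval 0.0537 to 0.335). The lower share was thus not particular to CACGTG, and it cannot tell that explanation from other properties of the sequence at these genes. At 80 tRNA genes a summit lay inside the gene, so the sequence searched there was partly that of the gene. Signal of neighbouring promoters was not enough to give the tRNA peaks, since 97 of 273 tRNA genes over 2000 bp from any protein-coding 5' end had a peak, against 5.47 at random. Binding of MDL-1 through another factor stays open, as untested.

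The higher peak density on chromosome X was not matched by more CACGTG there, at 139 per Mb against 185 per Mb on autosomes. Peaks without CACGTG kept a ratio of 1.31, above the 0.812 that bounds the promoter-weighted placements, which argues against hexamer density as the source. With at most 1 peak per 10 kb the ratio was 1.26, against an upper bound of 0.820, which argues against a few clusters. Mappability may still contribute and was not tested. The copy number of X in these animals of both sexes was not measured.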

How the results depend on the processing

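Added after seeing the data were the settings with every transcript 5' end, tRNA genes far from 5' ends, at most 1 peak per 10 kb and peaks without CACGTG. The promoter share, the X ratio, the CACGTG share and its quartile difference kept their direction and their side of 0.05 under every setting run. Their ranges were 41.5 to 64%, 1.26 to 1.34, 7.86 to 17.4% for CACGTG itself and odds ratios of 2.37 to 3.35. With the first or last base of the hexamer left free, the share was 25%, against 9.01% in the flanks. The promoter share of 64% came with the window of 2000 bp upstream and 500 bp downstream, against 39.2% at random. tRNA and microRNA counts stayed above random under every setting listed for them, while microRNA genes with a summit within 200 bp did not pass (10, permutation p = 0.150). The tRNA count was 103 with the 1935 highest IDR peaks, 80 with summits inside the gene and 97 for the far genes, and the microRNA count was 18 with those 1935 and 55 with the longer pooled list, as fewer or more peaks or genes entered. Shared top peaks came to 57.2% with summits within 50 bp, 54.2% in the highest 7740 and 63.2% when intervals had to overlap by 50% of each, and the scores' rho was 0.651 with summits within 50 bp and 0.543 in the 1935 highest; the cause was not tested. At mdl-1, the pooled list held 11 relaxed peaks in 100 kb, a wider window, and single replicates held 0 to 3 in 40 kb. The number of gene lists passing ran from 14 to 22, and 6 calls of single lists were lost over all settings: mitochondrial ribosomal and muscle genes with the 1935 highest peaks, vacuolar ATPase genes with matched random lists and among genes with a symbol, and neuropeptides with matched lists and with nearest 5' ends. Unknown depth limits the reading of absent peaks, since each relaxed list ends at 30000. No paired analysis was possible because the series has 1 group.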

Other observations

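All tests in this part were chosen after the main results were seen, and the values are given without an explanation. The octamer AGACGCAG had the lowest p of 1002 octamers present in at least 1% of IDR peaks. It lay within 50 bp of 460 summits (11.9%) and in 53 of 7740 flanking windows (0.685%), an odds ratio of 19.6 (Fisher's exact test, adjusted p = 3.8e-161), though some rarer octamers had higher odds ratios, with 10.8% in the highest 3870 peaks of replicate 1 and 10.5% in those of replicate 2. It was less common in peaks with CACGTG (8.45%) than in those without (12.4%; odds ratio 0.651, Fisher's exact test, p = 0.00994). GAGAGAGA lay at 6.64% of peaks against 0.711% of flanks. The full palindromes around the E-box were GCACGTGC (24 peaks and 3 flanking windows, odds ratio 16.1), TCACGTGA (52 peaks, odds ratio 8.77), ACACGTGT (22 peaks, odds ratio 5.53) and CCACGTGG (38 peaks, odds ratio 2.55), and differences between them were not tested.

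The replicates differed in where CACGTG lay. Among the 1263 peaks in the highest 3870 of replicate 2 that were not among the highest 3870 of replicate 1, 3.17% held CACGTG (exact 95% interval 2.27 to 4.29%). Among the 1263 in the highest 3870 of replicate 1 that were not among those of replicate 2, 14.4% did (12.5 to 16.5%). Of these peaks, 477 of replicate 2 and 487 of replicate 1 were missing from all relaxed peaks of the other replicate, and 2.31% and 12.5% of them held CACGTG. In every quartile of each list's own score, the share among the 1263 peaks was higher in replicate 1. In the top quartile it was 32% (16 of 50 peaks, exact 95% interval 19.5 to 46.7%) against 4% (1 of 25, 0.101 to 20.4%). These counts are small and the intervals overlap. In the lowest quartile it was 9.52% (58 of 609) against 3.09% (20 of 648). Over IDR peaks found in both, the median log2 ratio of replicate 1 to replicate 2 score was 0.79 at peaks with CACGTG and 0.38 at the others. For AGACGCAG the medians were 0.42 at peaks with the octamer and 0.43 at the others.

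Further peaks of network genes lay beyond their promoter windows. A peak of score 278 with CACGTG stood 1858 bp upstream of mml-1 (chromosome III, 7376453 to 7376742) and ranked 92 and 72 in the replicates. Another of score 139.7 with CACGTG stood 2875 bp upstream of mxl-3 (chromosome X, 13353611 to 13353747), with ranks of 628 and 278. In hlh-30, 1 of the 7 intronic peaks held CACGTG, at position 4026068 with a score of 183. The longest span without relaxed peaks was on chromosome V in all 3 relaxed lists: it ran from 2341029 to 2569617 in replicate 1 and from 2340524 to 2565822 in replicate 2, and held 50 protein-coding 5' ends in each.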
